A study of Seriola dumerili with 12 samples.

How the data were processed

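The data are bulk RNA sequencing of gill and kidney from juvenile greater amberjack held for 72 h at 10, 30 or 40 ppt salinity. There were 12 libraries in 6 groups, with 2 libraries per group. Replicates carried the numbers 1 and 2, except kidney at 10 ppt, which carried 1 and 3. Per the labels' protocols, the fish were 3 months old and were kept in 12 tanks with 10 fish per tank, and 6 fish were taken per salinity with both tissues from each. Total RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra RNA kit for Illumina. Neither the fish behind each library nor any pooling of fish is stated, so p-values measure only the spread between these samples. The protocols say that the 30 ppt control was natural seawater and that 10 and 40 ppt water was made from commercial sea salt and tap water. They also say that water of all 3 salinities was made with the salt. Salinity and water source therefore cannot be told apart in any comparison with 30 ppt if the first statement holds, whereas both groups of the 10 against 40 ppt comparisons had water of the same source.

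The deposited table holds raw counts, which the authors made, per the submitters' processing notes, with FastQC, HISAT2 and featureCounts. Their versions, the genome build, the annotation and the strand setting are not given in the sources used here. The table has 25284 genes, of which 661 were at 0 in every library. Of these genes, 22004 carried identifiers found in the RefSeq gene table of the species and 3280 were new gene models of the authors. A further limit on naming is that 11669 of the genes carried only a LOC identifier, and 10142 had a usable symbol. The table of the species placed no gene on a chromosome, so no positions are given. Total counts ranged from 3.19e+07 to 4.19e+07 per library, and the most abundant gene took 1.05 to 1.96% of the counts. Genes with a count of 1 (46 to 78 per library) were rarer than genes with a count of 2 (347 to 455), a feature whose origin is not given in the sources used here. Floors on folds cover counting error only and take each count as independent, which was not checked.

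Each tissue was fitted separately over its 6 libraries in R 4.3.3 with edgeR 4.0.16, using the quasi-likelihood test, TMM scaling and the filterByExpr defaults (count minimum 10, total minimum 15). This left 20787 genes in gill and 20836 in kidney. The 3 comparisons per tissue were 10 against 30 ppt, 40 against 30 ppt and 10 against 40 ppt. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 in a 2-sided test. Fold changes are edgeR log2 fold changes with their standard error (SE), levels are CPM, that is counts scaled to library size, as mean and SD, and n = 2 libraries per group throughout. The difference in salinity response between gill and kidney was tested as an interaction in a fit of all 12 libraries, over 22358 genes. Against a group at 0 in both libraries, the fold was computed from a floor of 3 counts over the group and is given as a lower bound.

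Gene lists numbered 45, of which 28 were processes and 17 were markers of cell types that gill or kidney pieces can hold. Members were matched by symbol alone, so no list held genes with only a LOC identifier. Lists with at least 5 tested genes (40 in gill, 38 in kidney) were tested with camera in limma 3.58.1, with a preset correlation of 0.01 on log2 CPM with a prior count of 2, and adjusted over the lists of a comparison. Members were also counted as called over all genes and as called when adjusted over the list alone. Alternatives were camera with an estimated correlation, and fry, which tests whether the genes of a list move one way on balance. With an estimated correlation, no list in any of the 6 comparisons had an adjusted p under 0.05.

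For each comparison with 30 ppt, the rule for named genes took the 6 largest rises and the 6 largest falls among called genes that had a symbol, a mean of at least 5 CPM and both libraries outside the control range in the same direction. It added up to 18 called list genes, at most 3 per list, and a set of transporter and hormone receptor genes whether called or not. For each interaction it took the 5 genes with the smallest p. Of the 7 transporter and receptor genes asked for per tissue, 5 were tested in gill and 3 in kidney, and the others were not among the tested genes under those symbols. The genes named in the 10 against 40 ppt comparisons, the other single genes named in kidney, chp1, col10a1 at 10 ppt, the single members named within lists where they were not called, and the choice of lists described in most detail were picked after their values were seen.

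Alternatives were DESeq2 1.42.0 size factors, library size alone, no filter on low counts, DESeq2's Wald test, limma-voom, only the 4 libraries compared, all 12 libraries, a log2 fold change of at least 1, replicate number as a block, and leaving out each library in turn. Halving the counts and, for the interactions, limma-voom and a block of gill and kidney libraries of the same salinity and number were alternatives added after seeing the data. Libraries of gill and kidney with the same salinity and number deviated together, with correlations of 0.217 at 30 ppt and 0.361 at 40 ppt across 19380 genes, which are not independent replicates. Each value stands for 2 pairs, because with n = 2 the deviations of both replicates mirror each other. As the protocol takes both tissues from each fish, these numbers were treated as pairs in the blocked interaction fits, a choice made after the calls of those fits were seen. At 10 ppt the tissues share only number 1. The shared control of both comparisons of a tissue was handled with 20 simulations per tissue, in which unchanged groups were compared with a shared simulated control, and 20 more for gill in which each salinity had effects of its own.

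The workflow was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. In the gill 10 against 30 ppt comparison, edgeR recovered 41 and 94 of these, with 20 false calls among 155. In the kidney 10 against 30 ppt comparison it recovered 4 and 72, with 12 false calls among 88, and in the 10 ppt interaction 1 and 55, with 6 false calls among 62. DESeq2 recovered 69 and 99 in gill with 80 false calls among 248, and 45 and 96 in kidney with 87 false calls among 228. With limma-voom 42 and 92 were recovered in gill with 15 false calls among 149, and 4 and 70 in kidney with 9 among 83. In each of these runs, those of edgeR included, the share of false calls was above the adjusted p threshold of 0.05. Camera found a planted list of 20 genes changed 1.5-fold in both tissues, with 0 false lists. Genes were simulated independently of each other, so this does not test the preset correlation on which the list calls depend. The other comparisons were not simulated. No library was left out of the comparisons, and no reads were realigned.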

Results

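Gill and kidney of juvenile greater amberjack (Seriola dumerili), a marine teleost, were sequenced after 72 h at 10, 30 or 40 ppt, with n = 2 libraries per tissue and salinity. Total counts were 3.23e+07 to 4.19e+07 in gill and 3.19e+07 to 3.86e+07 in kidney. Spearman's correlation between replicates, across genes, was 0.977 to 0.985 in gill and 0.966 to 0.975 in kidney. Between libraries of different salinities it was 0.968 to 0.981 in gill and 0.955 to 0.976 in kidney, so some such pairs were above the replicates. In kidney, 10 ppt replicate 3 and 40 ppt replicate 2 were at 0.976, against 0.966 for the 10 ppt replicates. The biological coefficient of variation was 0.250 in gill and 0.332 in kidney. The comparisons ask which genes differ between each changed salinity and the 30 ppt control in each tissue, and which differ between 10 and 40 ppt. Errors after CPM values are SD.

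In gill at 10 ppt, 2 of the 6 NaCl secretion genes fell against 30 ppt. The chloride channel gene cftr was 3.45-fold lower (33.9 ± 0.622 against 117 ± 9.86 CPM, log2 -1.79, SE 0.17, edgeR adjusted p = 0.0216). The Na-K-2Cl cotransporter gene slc12a2 was 2.09-fold lower (121 ± 3.69 against 253 ± 36.2 CPM, log2 -1.06, SE 0.13, adjusted p = 0.0455). In the opposite direction, the apical sodium/proton exchanger gene slc9a3 was 2.05-fold higher (484 ± 34.9 against 236 ± 1.85 CPM, adjusted p = 0.0355). The gene chp1, whose product binds sodium/proton exchangers, was 2.81-fold higher (414 ± 5.75 against 147 ± 6.51 CPM, adjusted p = 0.0181). Of the 6 NaCl secretion genes tested, 3 fell and 0 rose adjusted over the list alone. The list was not called, at a median log2 fold change of -0.25 (camera adjusted p = 0.0985). Of the 7 ion uptake and acid-base genes, 1 rose over all genes and 2 rose adjusted over the list alone (median 0.56, camera adjusted p = 0.0509). Not called were atp1b1, a sodium pump subunit (log2 -0.72, adjusted p = 0.239), and prlr, the prolactin receptor (0.97, adjusted p = 0.0603). Nor was slc12a3, with counts of 10 and 51 against 20 and 4 (1.20, SE 1.23, adjusted p = 0.734). The cftr adjusted p was 0.0544 to 0.204 when any 1 of the 4 libraries was left out, highest without 10 ppt replicate 1. Its log2 fold change stayed between -1.87 and -1.70. Without 1 library, the adjusted p was 0.0453 to 0.302 for slc12a2, 0.0709 to 0.214 for slc9a3 and 0.0374 to 0.0986 for chp1, each highest without 10 ppt replicate 1. The calls of slc12a2 and chp1 were kept only without 30 ppt replicate 2, and that of slc9a3 in none of the 4 runs. The uncalled slc12a3 value was -0.49 without 10 ppt replicate 2.

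Matrix and skeletal transcripts rose in gill at 10 ppt, where neither the water source nor the share of cartilage in the pieces was separated from salinity. The type I collagen gene col1a2 was 4.43-fold higher (2898 ± 351 against 653 ± 103 CPM, adjusted p = 0.0216). The gene col10a1, a collagen of hypertrophic cartilage, was also 4.43-fold higher (1251 ± 107 against 282 ± 47.6 CPM, adjusted p = 0.0181). Further rises were in ucma, a cartilage matrix protein gene (4.67-fold, log2 SE 0.11, adjusted p = 0.00378), col11a1, a cartilage collagen (5.17-fold, adjusted p = 0.0242), and bglap, encoding osteocalcin of bone. The last had counts of 360 and 242 against 0 and 4 (log2 6.90, SE 0.70, adjusted p = 0.0283), and its log2 fold change was 5.86 without 30 ppt replicate 1 and 11.12 as fitted without 30 ppt replicate 2, which leaves the control at 0. Also higher were mmp2, a gelatinase gene (2.59-fold, adjusted p = 0.0272), col6a3 (2.25-fold, adjusted p = 0.0401), igsf10 (log2 2.32, adjusted p = 0.0425) and sostdc1, encoding a BMP and Wnt antagonist (5.67-fold, adjusted p = 0.0354). Of 18 extracellular matrix genes, 4 rose over all genes and 17 adjusted over the list alone. All 18 had positive values (median log2 0.92, camera adjusted p = 3.45e-21, adjusted p = 0.617 with an estimated correlation). Of 12 cartilage and bone markers, 3 rose over all genes and 9 adjusted over the list alone (median 1.63, camera adjusted p = 1.81e-10, adjusted p = 0.617 with an estimated correlation). The aggrecan gene acan was at 0.33 (SE 0.20, adjusted p = 0.554). The call of ucma was kept without any 1 library (highest adjusted p 0.0418). The others named here lost theirs without at least 1 library. Without 10 ppt replicate 1, adjusted p was 0.153 for col1a2 and bglap, 0.109 for col10a1, 0.117 for col11a1, 0.204 for mmp2 and sostdc1, 0.280 for col6a3 and 0.261 for igsf10. All 8 also lost it without 10 ppt replicate 2. Without 30 ppt replicate 1 only bglap kept it, and without 30 ppt replicate 2 only bglap, col10a1 and col11a1 did.

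Other falls in gill at 10 ppt were in greb1l (6.11-fold lower, 7.62 ± 1.85 against 46.5 ± 16.5 CPM, edgeR adjusted p = 0.0450) and lynx1. The latter encodes a modulator of nicotinic acetylcholine receptors (5.71-fold lower, 104 ± 21.3 against 592 ± 67.6 CPM, adjusted p = 0.0181). The autophagy kinase gene ulk2 was 3.13-fold lower (adjusted p = 0.0479) and the COPI coat gene copb2 was 2.11-fold lower (adjusted p = 0.0455). All 20 TCA cycle genes had values below 0 (median log2 -0.19, 0 called, camera adjusted p = 9.38e-05, adjusted p = 0.617 with an estimated correlation). Camera also called ER stress genes lower (median on log2 CPM -0.27, adjusted p = 0.00146), as well as oxidative phosphorylation (-0.12) and ribosomal protein genes (-0.09, adjusted p = 0.00446 for both). The ER stress median was 0.005 without 30 ppt replicate 2. The oxidative phosphorylation median was -0.07 without 30 ppt replicate 2 and -0.03 without 10 ppt replicate 2. The ribosomal median was -0.03 without 30 ppt replicate 1 and -0.06 without 10 ppt replicate 2. Each of these list calls was lost in the runs given. The ribosomal list as matched also holds 4 S6 kinase or binding protein genes. Of 21 cholesterol synthesis genes, 20 had values below 0 (median -0.72, 0 called, camera adjusted p = 0.00446, adjusted p = 0.765 with an estimated correlation). That list rested on 1 control library: computed on log2 CPM, its median was -0.51 with all libraries and 0.19 without 30 ppt replicate 2 (camera adjusted p = 0.199). Without 10 ppt replicate 1, the adjusted p was 0.286 for greb1l and 0.302 for ulk2 and copb2, and without 10 ppt replicate 2 it was 0.0817 for lynx1. Of these 4, only lynx1 kept its call without 30 ppt replicate 1, only lynx1 and ulk2 without 30 ppt replicate 2, and none without either 10 ppt library. The cholesterol list also lost its call without 10 ppt replicate 1 (camera adjusted p = 0.0629).

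In all, edgeR called 80 of 20787 genes in gill at 10 against 30 ppt, 61 higher and 19 lower, of which 30 had a symbol. At an unadjusted p under 0.05 there were 2669 genes. The count was 11 and 15 without 10 ppt replicate 1 and 2, and 13 and 38 without 30 ppt replicate 1 and 2. Without 30 ppt replicate 1, 46.2% of the calls were higher, against 76.2% with all libraries. Most of these runs also called genes outside the 80. All 80 genes kept their direction in each of these runs, which is weak support because they were selected in a fit holding the same libraries. DESeq2 called 903 genes, and a fit of only the 4 libraries compared called 30.

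In gill at 40 ppt, matrix and skeletal genes were again higher than at 30 ppt, with the same limits. The gene col10a1 rose 6.75-fold (1904 ± 165 against 282 ± 47.6 CPM, edgeR adjusted p = 0.0133) and col1a2 6.11-fold (3993 ± 697 against 653 ± 103 CPM, adjusted p = 0.0157). Higher too were col11a1 (6.21-fold, adjusted p = 0.0169) and col22a1, a collagen of tissue junctions (5.20-fold, adjusted p = 0.0157). Also higher were col6a3 (2.86-fold, adjusted p = 0.0187), mmp2 (2.67-fold, adjusted p = 0.0206) and igsf10 (5.82-fold, adjusted p = 0.0278). So was bglap (log2 6.97, SE 0.70, counts of 239 and 306 against 0 and 4, adjusted p = 0.0221), with 5.94 without 30 ppt replicate 1 and 11.18 as fitted without 30 ppt replicate 2, which leaves the control at 0. Of 18 extracellular matrix genes, 9 rose over all genes and 18 adjusted over the list alone (median log2 1.19, camera adjusted p = 5.36e-25, adjusted p = 0.687 with an estimated correlation). Of 12 cartilage and bone markers, 4 rose over all genes and 8 adjusted over the list alone (median 2.18, camera adjusted p = 5.09e-11, adjusted p = 0.687 with an estimated correlation). The falls named were greb1l (5.48-fold lower, adjusted p = 0.0423) and clec3a, a lectin gene of cartilage (2.13-fold lower, 37.6 against 80.1 CPM, log2 SE 0.11, adjusted p = 0.0221). The calls of all 10 of these genes were lost without 30 ppt replicate 1 (adjusted p 0.0619 to 0.120 over the named calls) and without 40 ppt replicate 2 (0.106 to 0.189). Without 40 ppt replicate 1 only col1a2 and col10a1 kept theirs, and without 30 ppt replicate 2 all but mmp2 and col6a3 did. Skeletal muscle markers also lay higher at 40 ppt (10 genes, 0 called, median 0.56, camera adjusted p = 0.0295, adjusted p = 0.809 with an estimated correlation). Their median on log2 CPM was 0.63 with all libraries, 0.15 without 30 ppt replicate 1 (camera adjusted p = 0.428), 0.27 without 40 ppt replicate 2 (camera adjusted p = 0.344) and 1.10 without 30 ppt replicate 2. Chromaffin markers lay lower (7 genes, all below 0, 0 called over all genes, 1 fell adjusted over the list alone, median -0.49, camera adjusted p = 0.0262, adjusted p = 0.809 with an estimated correlation). That call was lost without 30 ppt replicate 1 (median on log2 CPM -0.21 against -0.48 with all libraries, camera adjusted p = 0.283), 40 ppt replicate 1 (-0.43, camera adjusted p = 0.0508) and 40 ppt replicate 2 (-0.36, camera adjusted p = 0.0941).

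Immediate early genes, which respond quickly to stimuli, lay higher in gill at 40 than at 30 ppt. The transcription factor gene egr1 rose 2.34-fold (159 ± 3.90 against 67.9 ± 7.04 CPM, edgeR adjusted p = 0.0253). Its adjusted p was 0.0620 to 0.150 when any 1 of the 4 libraries was left out, highest without 40 ppt replicate 2. All 17 genes of the list had values above 0, 1 rose over all genes and 4 adjusted over the list alone (median log2 0.60, camera adjusted p = 5.01e-07, adjusted p = 0.687 with an estimated correlation). Of the genes in the lists for NaCl secretion, ion uptake, renal ion transport, V-type ATPase and aquaporins, 0 were called at 40 ppt, where 46 of the 109 called genes had a symbol. The gene cftr was at 172 ± 35.3 CPM (log2 0.56, adjusted p = 0.231) and slc12a2 at 323 ± 5.59 CPM (0.35, adjusted p = 0.332). The pump subunit gene atp1b1 was at 558 ± 70.9 CPM (-0.61, adjusted p = 0.288), prlr at 33.5 ± 1.52 CPM (-0.56, adjusted p = 0.178). For slc12a3 there were counts of 0 and 4 (-2.53, SE 1.51, adjusted p = 0.531). Of the 6 NaCl secretion genes, 0 were called over all genes, while 4 rose and 1 fell adjusted over the list alone (median 0.53, camera adjusted p = 0.0359, adjusted p = 0.809 with an estimated correlation). That call was lost without 30 ppt replicate 2 (median on log2 CPM 0.32 against 0.53 with all libraries, camera adjusted p = 0.317) and without 40 ppt replicate 1 (0.45, camera adjusted p = 0.0885). Ribosomal protein genes lay lower (median on log2 CPM -0.12, camera adjusted p = 0.000459). The ribosomal call was lost without 30 ppt replicate 1, where the median was -0.03. Oxidative phosphorylation genes had a median of 0.17 (54 genes, 0 called, camera adjusted p = 0.0161, adjusted p = 0.809 with an estimated correlation). That call was lost without 30 ppt replicate 1 (median on log2 CPM 0.11, camera adjusted p = 0.260) and without 40 ppt replicate 1 (0.11, camera adjusted p = 0.259).

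For gill at 40 against 30 ppt, edgeR called 109 genes, 96 higher and 13 lower, of which 46 had a symbol. In all 2810 genes had an unadjusted p under 0.05. The count was 0 without 30 ppt replicate 1, 84 without 30 ppt replicate 2, 22 without 40 ppt replicate 1 and 0 without 40 ppt replicate 2. The runs with calls also called genes outside the 109. All 109 genes kept their direction in each run, which is weak support because they were selected in a fit holding the same libraries. For the runs without any call, the genes at an unadjusted p under 0.05 numbered 2645 and 1927. DESeq2 called 993 genes and limma-voom 96, and a fit of only the 4 libraries compared called 3.

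**Figure D1:**
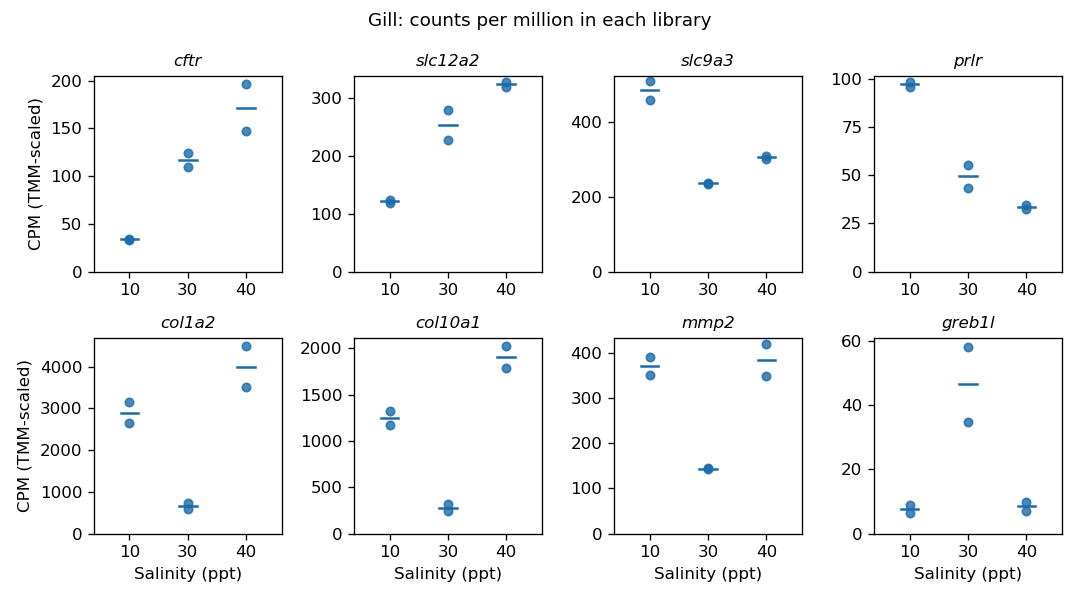
CPM of 8 genes in each gill library by salinity, with dots for libraries and a bar for the mean of the 2 libraries of a group. The gene cftr sat at a mean of 33.9, 117 and 172 CPM at 10, 30 and 40 ppt, and col1a2 at 2898, 653 and 3993 CPM.

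Comparing gill at 10 and 40 ppt directly, without the control, cftr was 5.07-fold lower at 10 ppt (33.9 ± 0.622 against 172 ± 35.3 CPM, log2 -2.34, SE 0.17, edgeR adjusted p = 0.0252). The prolactin receptor gene prlr was 2.90-fold higher at 10 ppt (97.2 ± 1.55 against 33.5 ± 1.52 CPM, adjusted p = 0.0491), and chp1 was 2.47-fold higher (adjusted p = 0.0336). The gene slc12a2 was 2.66-fold lower in value (121 ± 3.69 against 323 ± 5.59 CPM) at an adjusted p of 0.0517 and was not called. Of the 6 NaCl secretion genes, all had values below 0, 1 fell over all genes and 2 fell adjusted over the list alone (median log2 -0.51, camera adjusted p = 1.02e-05, adjusted p = 0.574 with an estimated correlation). Oxidative phosphorylation genes lay lower at 10 ppt (54 genes, 0 called over all genes and 0 adjusted over the list alone, median -0.28, camera adjusted p = 2.08e-11, adjusted p = 0.574 with an estimated correlation). So did TCA cycle genes (20 genes, 0 called, 3 fell adjusted over the list alone, median -0.22, camera adjusted p = 7.23e-07, adjusted p = 0.574 with an estimated correlation). All 17 immediate early genes lay lower at 10 ppt, of which 0 were called over all genes and 5 fell adjusted over the list alone (median -0.49, camera adjusted p = 1.08e-10, adjusted p = 0.574 with an estimated correlation). The matrix list lay lower at 10 than at 40 ppt (18 genes, 0 called, median -0.29, camera adjusted p = 5.77e-05, adjusted p = 0.754 with an estimated correlation). On log2 CPM its median was -0.29 with all libraries, -0.20 without 10 ppt replicate 2 (camera adjusted p = 0.0511), -0.12 without 40 ppt replicate 2 (camera adjusted p = 0.263) and -0.46 without 40 ppt replicate 1. The cftr call was lost without 10 ppt replicate 1 (adjusted p = 0.250) or replicate 2 (0.275). Without 1 library the adjusted p was 0.212 to 0.290 for chp1 and 0.233 to 0.313 for prlr, so both calls were lost in each of the 4 runs.

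The 12 genes called between gill at 10 and 40 ppt (5 higher and 7 lower at 10 ppt, 1388 at an unadjusted p under 0.05) included 9 without a symbol. The gene LOC111239963 stood at 502 ± 22.9 CPM at 10 ppt, 0.216 ± 0.0436 at 30 ppt and 0.131 ± 0.0340 at 40 ppt (adjusted p = 2.51e-05). The same order gave LOC111240219 at 57.0, 8.86 and 5.29 CPM (counts of 2357 and 2222, 331 and 280, and 162 and 208). The gene LOC111239725 had 0 counts in both 10 ppt libraries, at least 176-fold lower than at 40 ppt and at least 180-fold lower than at 30 ppt. The gene LOC111236848 followed salinity, at 7.12 ± 0.162, 40.9 ± 2.09 and 112 ± 11.4 CPM (adjusted p = 0.000583). It was the 1 gene called in opposite directions against 30 ppt at 10 and 40 ppt. In kidney, LOC111239963 had at most 16 counts in any library, LOC111240219 had 817 and 0 counts at 10 ppt, and LOC111239725 had 0 and 31. A difference in genotype between fish was not tested for these 3 genes and is not separated from salinity. The count was 10 and 7 without 10 ppt replicate 1 and 2, and 10 and 4 without 40 ppt replicate 1 and 2. Most of these runs also called genes outside the 12 found with all libraries. DESeq2 called 275 genes.

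In kidney at 10 ppt, edgeR called 0 of 20836 genes against 30 ppt, with 2685 at an unadjusted p under 0.05. The edgeR self-test recovered few 2-fold changes in this tissue, with 12 false calls among 88. DESeq2 called 988 genes, with 87 false calls among 228 in its self-test, and limma-voom called 2. An edgeR fit of all 12 libraries called 170. The list with the smallest camera p was that of matrix genes. The gene col1a2 stood at 388 ± 50.8 against 138 ± 13.9 CPM (log2 1.49, SE 0.18, adjusted p = 0.143). Of 18 extracellular matrix genes, 0 were called over all genes and 11 rose adjusted over the list alone (median log2 0.71, camera adjusted p = 1.02e-08, adjusted p = 0.509 with an estimated correlation). Immediate early genes lay lower (17 genes, 0 called, 1 fell adjusted over the list alone, median -0.57, camera adjusted p = 0.00132, adjusted p = 0.509 with an estimated correlation). Among single genes, greb1l was at 44.4 against 306 CPM (log2 -2.78, SE 0.30, adjusted p = 0.143), and the clock gene per1 at 90.6 ± 9.83 against 242 ± 4.81 CPM (-1.42, adjusted p = 0.143). The thiazide-sensitive cotransporter gene slc12a3 was at 278 ± 12.2 against 722 ± 79.8 CPM (-1.38, adjusted p = 0.356). The loop-type cotransporter gene slc12a1 (-0.19, adjusted p = 0.786) and the anion exchanger gene slc26a6 (0.30, adjusted p = 0.657) had smaller values.

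Markers of cell types were tested in kidney at 10 ppt. Proximal tubule markers lay higher (15 genes, 0 called over all genes, 2 rose adjusted over the list alone, median log2 0.35, camera adjusted p = 0.00538, adjusted p = 0.743 with an estimated correlation). On log2 CPM their median was 0.37 with all libraries and 0.16 without 10 ppt replicate 1 (camera adjusted p = 0.307), and the call was also lost without 30 ppt replicate 2 (0.32, camera adjusted p = 0.0635). It was 0.56 without 10 ppt replicate 3. Podocyte markers also lay higher (7 genes, 0 called over all genes, 3 rose adjusted over the list alone, median 0.46, camera adjusted p = 0.00538, adjusted p = 0.674 with an estimated correlation). T and NK cell markers lay lower (6 genes, 0 called over all genes, 1 fell adjusted over the list alone, median -0.93, camera adjusted p = 0.00538, adjusted p = 0.681 with an estimated correlation). On log2 CPM this median was -0.85 with all libraries, -0.42 without 30 ppt replicate 2 (camera adjusted p = 0.0635) and -1.37 without 30 ppt replicate 1. Neutrophil and macrophage markers lay lower (12 genes, 11 below 0, 0 called, median -0.30, camera adjusted p = 0.0192, adjusted p = 0.674 with an estimated correlation), a call lost without 30 ppt replicate 2 (camera adjusted p = 0.224). Haematopoietic progenitor markers lay higher (10 genes, 9 above 0, 0 called, median 0.49, camera adjusted p = 0.0338, adjusted p = 0.887 with an estimated correlation). On log2 CPM their median was 0.49 with all libraries, 0.10 without 10 ppt replicate 3 (camera adjusted p = 0.806), 0.18 without 30 ppt replicate 1 (camera adjusted p = 0.433) and 1.03 without 10 ppt replicate 1. Liver genes moved with the same comparison. The hepatocyte list, with plasma protein genes such as fgb and ttr, had a median of -4.85 (12 genes, 0 called over all genes, 9 fell adjusted over the list alone, camera adjusted p = 4.91e-08, adjusted p = 0.674 with an estimated correlation). The list's median per library was 4.38 (log2, relative to the tissue mean) in 30 ppt replicate 2 and 1.33 in 30 ppt replicate 1, against -1.78 to -1.36 in the other 4 kidney libraries. Computed on log2 CPM, the list's median was -4.08 with all libraries and -2.40 without 30 ppt replicate 2. Skeletal muscle markers had a median of -2.54 (8 genes, 0 called, camera adjusted p = 0.00538, adjusted p = 0.743 with an estimated correlation), with library medians from -3.10 in 10 ppt replicate 1 to 1.82 in 30 ppt replicate 1. That call was lost without either of these libraries (median on log2 CPM -1.60 and -1.68 against -2.69 with all, camera adjusted p = 0.0783 and 0.0990).

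In kidney at 40 ppt, edgeR again called 0 of 20836 genes against 30 ppt, with 2063 at an unadjusted p under 0.05, while DESeq2 called 657, limma-voom 0 and an edgeR fit of all 12 libraries 143. The matrix genes lay higher, again with the water source not separated from salinity, and col1a2 was at 605 ± 44.1 against 138 ± 13.9 CPM (log2 2.13, SE 0.19, adjusted p = 0.0861). Of 18 extracellular matrix genes, 0 were called over all genes and 14 rose adjusted over the list alone (median 0.93, camera adjusted p = 2.38e-17, adjusted p = 0.402 with an estimated correlation, fry adjusted p = 0.0354). The bone gene bglap had 18 and 233 counts, against 0 in both libraries at 30 ppt and 0 and 4 at 10 ppt. Immediate early genes lay higher (17 genes, 0 called over all genes, 5 rose adjusted over the list alone, median 0.35, camera adjusted p = 0.00910, adjusted p = 0.816 with an estimated correlation). Among them cyr61 was at 120 ± 0.656 against 36.1 ± 3.49 CPM (1.73, adjusted p = 0.137). Cell cycle genes lay higher (39 genes, 36 above 0, 0 called, median 0.56, camera adjusted p = 9.22e-05, adjusted p = 0.894 with an estimated correlation). Without 30 ppt replicate 1 their median on log2 CPM was 0.21 against 0.58 with all libraries (camera adjusted p = 0.548). Without 30 ppt replicate 2 it was 1.04. Haematopoietic progenitor markers also lay higher (10 genes, all above 0, 0 called, median 0.69, camera adjusted p = 0.000427, adjusted p = 0.871 with an estimated correlation). Their call was likewise lost without 30 ppt replicate 1, where the median on log2 CPM was 0.47 against 0.74 with all libraries (camera adjusted p = 0.0583). Hepatocyte markers had a median of -6.14, or -5.22 with the 4 genes that were at 0 in a group set at their floor (9 of 12 fell adjusted over the list alone, camera adjusted p = 3.14e-10, adjusted p = 0.860 with an estimated correlation). Values for single transporters were -0.40 for slc12a3 (adjusted p = 0.819), 0.14 for slc12a1 (adjusted p = 0.873) and 0.10 for slc26a6 (adjusted p = 0.915). The slc12a3 value was 0.19 without 40 ppt replicate 2. The slc12a1 value was -0.0046 without 30 ppt replicate 1 and -0.09 without 40 ppt replicate 1, and that of slc26a6 was -0.07 without 30 ppt replicate 2 and -0.06 without 40 ppt replicate 2. The gene greb1l was at 122 ± 8.26 CPM (-1.32, adjusted p = 0.307).

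Between kidney at 10 and 40 ppt, the immediate early genes gave the list with the smallest camera p, where time and handling before sampling were not separated from salinity. All 17 lay lower at 10 ppt, of which 0 were called over all genes and 7 fell adjusted over the list alone (median log2 -0.82, camera adjusted p = 3.89e-12, adjusted p = 0.154 with an estimated correlation, fry adjusted p = 0.0245). The AP-1 gene fosb was at 0.463 ± 0.180 against 13.1 ± 4.59 CPM (-4.81, adjusted p = 0.246), cyr61 at 27.3 ± 6.12 against 120 ± 0.656 CPM (-2.14, adjusted p = 0.198) and egr1 at 11.9 ± 0.312 against 50.6 ± 11.6 CPM (-2.09, adjusted p = 0.683). Markers of cell types moved in the same comparison. Skeletal muscle markers lay lower at 10 ppt (8 genes, 6 below 0, 0 called, median -2.42, camera adjusted p = 0.00244, adjusted p = 0.804 with an estimated correlation). On log2 CPM their median was -2.78 with all libraries, -1.41 without 10 ppt replicate 1 (camera adjusted p = 0.150) and -1.85 without 40 ppt replicate 2. Proximal tubule markers lay higher (15 genes, 13 above 0, 0 called, median 0.30, camera adjusted p = 0.00244, adjusted p = 0.804 with an estimated correlation). On log2 CPM their median was 0.30 with all libraries, 0.07 without 10 ppt replicate 1 (camera adjusted p = 0.387), 0.24 without 40 ppt replicate 2 (camera adjusted p = 0.138) and 0.47 without 10 ppt replicate 3. Podocyte markers also lay higher (7 genes, 0 called over all genes, 1 rose adjusted over the list alone, median 0.16, camera adjusted p = 0.0238, adjusted p = 0.804 with an estimated correlation). That call was lost without 10 ppt replicate 1 (camera adjusted p = 0.177) and 40 ppt replicate 2 (camera adjusted p = 0.224), and the median on log2 CPM was 0.30 without 40 ppt replicate 1 against 0.16 with all libraries. Cell cycle genes lay lower (39 genes, 35 below 0, 0 called, median -0.38, camera adjusted p = 0.000223, adjusted p = 0.835 with an estimated correlation). Their median on log2 CPM was -0.50 with all libraries, 0.16 without 10 ppt replicate 1 (camera adjusted p = 0.177), -1.07 without 10 ppt replicate 3 and -0.32 without 40 ppt replicate 2. The 1 gene called by edgeR, LOC111225555, was at 298 ± 70.5 CPM at 10 ppt, 24.2 ± 4.52 at 30 ppt and 10.9 ± 0.752 at 40 ppt (log2 4.78 for 10 against 40 ppt, SE 0.26, adjusted p = 0.0476). With any 1 of the 4 libraries left out, edgeR called 0 genes, with 769 to 1946 at an unadjusted p under 0.05. With all libraries, 1198 genes had an unadjusted p under 0.05 and DESeq2 called 203. An edgeR fit of all 12 libraries called 16.

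**Figure D2:**
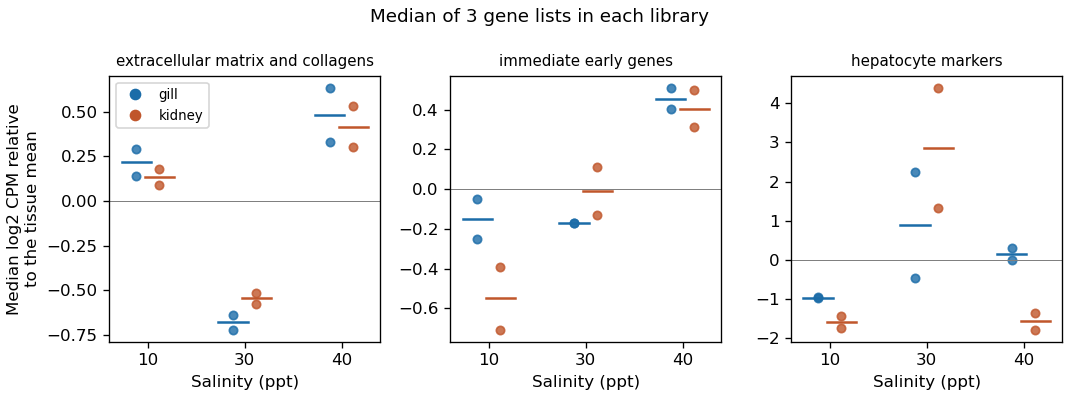
Median log2 level of the extracellular matrix, immediate early and hepatocyte lists in each library, relative to the mean of the tissue, by salinity in gill and kidney, with dots for libraries and a bar for the mean of a group. The matrix median was -0.72 and -0.64 in the gill libraries at 30 ppt and -0.52 and -0.58 in the kidney libraries at 30 ppt, and above 0 in all other libraries.

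Because both salinities were compared with the same controls, their overlap was set against simulations with unchanged groups. In gill, 49 genes were called higher and 4 lower at both salinities, and 1 in opposite directions, against simulated means of 0.1, 0.05 and 0. Those simulations called a mean of 2 and 1.35 genes, against 80 and 109 observed, so they set no bound on an overlap of lists of this size. Independent lists of the observed sizes would share 0.282 higher and 0.0119 lower genes. In simulations added after seeing the data, with the observed effects placed independently at each salinity against a shared control, 71 and 99.1 genes were called on average, and 2.15 higher, 0.8 lower and 0.25 opposite genes were shared (at most 4, 4 and 1). Across genes, which are not independent replicates, Pearson's r between the log2 fold changes was 0.617 in gill against 0.497 in the simulations, and 0.683 in kidney against 0.505. The covariance exceeded the simulated mean by 0.273 in gill and 0.505 in kidney. The control libraries were too few to split, so a deviation of the controls themselves from other fish at 30 ppt is not removed by these simulations. With 1 library left out, shared genes were counted anew in each run and can lie outside those shared with all libraries. The 53 shared genes of the same direction in gill numbered 0 without 30 ppt replicate 1 or 40 ppt replicate 2, 28 without 30 ppt replicate 2, 3 and 7 without 10 ppt replicate 1 and 2, and 10 without 40 ppt replicate 1.

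The genes called in gill were followed in kidney. Of the 72 tested among those called at 10 ppt, 57 (79.2%) had the same direction in kidney, against 58.4% of all 19380 genes, and 31 were called adjusted over the list alone, 30 of them in the same direction. Of the 100 tested among those called at 40 ppt, 93 (93%) had the same direction, against 63.1% of all genes, and 55 were called adjusted over the list alone, all in the same direction. With the matrix and skeletal lists removed, 51 of 65 and 80 of 87 genes had the same direction. The median kidney log2 fold change, signed by the gill direction, was 0.80 and 1.00. These values are not independent of those in gill where libraries of the same number share a fish, which is not given. In a check added after seeing the data, equally long lists of the largest gill differences were taken from libraries of 1 number. In kidney libraries of the same number, 70.8% had the same direction at 10 ppt and 71% and 78% at 40 ppt, against 57.1%, 59.6% and 62.1% of all genes tested. In those of another number it was 54.2% and 56.9% at 10 ppt, and 59% and 49% at 40 ppt, against 56.5% to 57.9% of all genes tested there. The signed median was 1.04, 1.18 and 1.51 for the same number. For another number it was mixed. Gill number 1 against kidney number 2 at 40 ppt gave 0.62, above the highest of 10000 lists drawn at random (0.41). The reverse gave 0, and 10 ppt gave 0.07 and 0.25, each below its highest random median. The lists of this check were chosen anew from 1 library per group, so it does not test the called genes themselves.

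The interaction tested whether the response differed between tissues, in a fit that treats gill and kidney libraries as independent although both tissues were taken from each fish. At 10 ppt, edgeR called 5 of 22358 genes, with 2168 at an unadjusted p under 0.05. The gene padi2, whose product converts arginine to citrulline in proteins, was at 134 ± 5.37 against 93.0 ± 4.71 CPM in gill and at 4.38 ± 1.10 against 19.5 ± 1.70 CPM in kidney (difference in log2 fold change 2.68, SE 0.24, adjusted p = 0.0286). The gene LOC111236848 fell with the lower salinity in gill and was at 302 ± 90.7 against 291 ± 23.1 CPM in kidney (-2.56, adjusted p = 0.0371). The gene LOC111228910 was at 5.59 ± 0.887 against 1.02 ± 0.132 CPM in gill and 1.77 ± 0.357 against 4.90 ± 0.243 in kidney (3.92, adjusted p = 0.0371). The new gene model newGene_1850 was at 0.605 ± 0.0277 against 0.276 ± 0.161 CPM in gill and 0.303 ± 0.0490 against 25.1 ± 15.3 in kidney (7.49, adjusted p = 0.0371). The new gene model newGene_11917 was at 2.44 ± 0.324 against 12.7 ± 0.512 CPM in gill, while in kidney both 10 ppt libraries were at 0, at least 117-fold lower than at 30 ppt (difference at least 4.51 with that group at its floor, adjusted p = 0.0286). Of these 5 calls, 0 were kept without 10 ppt replicate 1 or 2 or 30 ppt replicate 1 or 2 of gill, or without 30 ppt replicate 2 of kidney (adjusted p from 0.0639 to 0.213), and 2 were kept without each of 10 ppt replicate 1, 10 ppt replicate 3 and 30 ppt replicate 1 of kidney. The count of calls was 2 and 0 without gill 10 ppt replicate 1 and 2, 2 and 1 without gill 30 ppt replicate 1 and 2, 4 and 2 without kidney 10 ppt replicate 1 and 3, and 4 and 1 without kidney 30 ppt replicate 1 and 2. DESeq2 called 427 genes and limma-voom 1, padi2 (adjusted p = 0.0295). In limma-voom padi2 was also the 1 call with gill and kidney libraries of the same salinity and number as a replicate block.

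At 40 ppt, the interaction was called for 2 genes, with 1430 at an unadjusted p under 0.05. The gene gne, encoding the first enzyme of sialic acid synthesis, was at 38.8 ± 0.690 against 25.1 ± 0.227 CPM in gill and 18.1 ± 1.60 against 37.2 ± 0.936 CPM in kidney (difference 1.67, SE 0.17, edgeR adjusted p = 0.0425). The new gene model newGene_11917 was at 14.5 ± 3.51 against 12.7 ± 0.512 CPM in gill and 0.133 ± 0.00642 against 5.13 ± 0.553 in kidney (5.43, adjusted p = 0.0215). Not called, at an adjusted p of 0.112, were LOC111218037 (1.82), aqp4, an aquaporin gene at 0.832 ± 0.180 against 0.0842 ± 0.0343 CPM in gill and 320 ± 65.1 against 306 ± 17.5 CPM in kidney (3.17), and LOC111227848, at 0 in both gill libraries at 40 ppt and at least 92.2-fold lower there than at 30 ppt. Both calls were lost without each of the gill libraries at 30 and 40 ppt, without 30 ppt replicate 2 of kidney and without either 40 ppt library of kidney (adjusted p from 0.0523 to 0.196), and newGene_11917 was kept without 30 ppt replicate 1 of kidney (adjusted p = 0.0351). The count of calls was 4 without kidney 30 ppt replicate 1, 1 without gill 30 ppt replicate 2 or kidney 40 ppt replicate 2, and 0 without each of the other 5 libraries at 30 and 40 ppt. The 10 ppt libraries were not left out for this result. With gill and kidney libraries of the same salinity and number as a replicate block, edgeR called 0 genes (adjusted p = 0.489 for gne and 0.225 for newGene_11917, 1404 at an unadjusted p under 0.05). The terms of that block leave fewer residual degrees of freedom than the main fit has. DESeq2 called 140 genes and limma-voom 0, or 2 with the correlation within that block, gne (adjusted p = 0.0252) and LOC111218037 (0.0386).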

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

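The results below were listed because the test of the difference between gill and kidney passed, that is, the salinity response of a gene differed between the tissues. No explanation was tested for them, and the cause was not tested.

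At 10 ppt 5 genes passed, with differences in log2 fold change (gill minus kidney) of 2.68 for padi2, -2.56 for LOC111236848, 8.17 for newGene_11917 as fitted, 7.49 for newGene_1850 and 3.92 for LOC111228910. Because newGene_11917 was at 0 in kidney at 10 ppt, its fitted value is not a measured difference, and with that group at its floor the difference is at least 4.51. At 40 ppt 2 genes passed, newGene_11917 (5.43) and gne (1.67), and edgeR called 0 with gill and kidney libraries of the same salinity and number as a replicate block (adjusted p = 0.225 and 0.489). The blocked fit leaves fewer residual degrees of freedom than the main fit, which alone can cost calls. The padi2 difference came with a higher level in gill and a lower level in kidney at 10 ppt, and that of gne likewise at 40 ppt. The differences of both new gene models came with kidney levels far below those of the kidney controls, where newGene_1850 had an SD of 15.3 around a mean of 25.1 CPM.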

How the results depend on the processing

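The comparisons, gene lists, rule for named genes and alternatives were fixed before the data were examined. Halving the counts and, for the interactions, limma-voom and the block across tissues were added after. The fixed lists and rule also took genes without a symbol by their product description. That step was not run, so the lists and the largest rises and falls hold only genes with a symbol. With DESeq2's Wald test the counts of called genes were 903, 993 and 275 in gill (10 against 30, 40 against 30, 10 against 40 ppt), 988, 657 and 203 in kidney, 427 and 140 for the interactions at 10 and 40 ppt, and 491 and 340 for the overlap in gill and kidney. Without a low-count filter they were 157, 196 and 26 in gill and 7 in kidney at 40 against 30 ppt. With only the 4 libraries compared they were 30 and 3 in gill against 30 ppt, and 0 in kidney at 10 against 40 ppt. With all 12 libraries they were 170, 143 and 16 in kidney. With library size alone they were 1 in kidney at 10 against 30 ppt and 3 at 10 against 40 ppt, and limma-voom gave 2 in the former. DESeq2 size factors gave 2 and 1 for the interactions at 10 and 40 ppt. With replicate number as a block the counts were 9, 49 and 4 in gill. Halving the counts gave 96, 110 and 16 calls in gill and 0, 0 and 1 in kidney. Correlations of residuals between samples of the same number were 0.0238, -0.0590 and -0.0489 in gill and -0.0608 in kidney, so the numbers do not pair the samples within a tissue. For the interactions limma-voom gave 1 and 0 calls at 10 and 40 ppt, and 1 and 2 with the replicate block within salinity (consensus correlation 0.188). With that replicate block in edgeR the 40 ppt interaction had 0 calls, with 1404 at an unadjusted p under 0.05. No paired analysis was possible within kidney for 10 ppt against another salinity. These groups share only number 1, and a block would rest on that 1 pair. The 10 ppt interaction was blocked only in limma-voom, where the consensus correlation was taken over libraries of all salinities. Leaving out 1 library gave 11 to 38, 0 to 84 and 4 to 10 calls in gill, 0 to 0 in kidney at 10 against 40 ppt, 0 to 4 for each interaction and 0 to 28 for the gill overlap, where the lone sample is assumed to vary like the other groups. Without gill 30 ppt replicate 1, 46.2% of the calls at 10 against 30 ppt were higher. With the preset correlation, camera called 7, 8 and 10 lists in gill and 11, 7 and 7 in kidney, in the same order of comparisons. List calls with an estimated correlation were 0 in all 6 comparisons, and with fry 0 in gill and in kidney at 10 against 30 ppt and 1 in each other kidney comparison. Leaving out 1 library gave 5 to 12, 7 to 12 and 7 to 10 lists in gill and 8 to 15, 4 to 9 and 7 to 12 in kidney. Leaving out 1 library gave values of both signs for slc12a3 in gill at 10 ppt (-0.494 to 2.63, lowest without 10 ppt replicate 2 and highest without 30 ppt replicate 1). In kidney at 40 ppt this held for slc12a3 (-1.44 to 0.192, without 40 ppt replicate 1 and 2), slc26a6 (-0.0666 to 0.292, without 30 ppt replicate 2 and 1, and -0.0566 without 40 ppt replicate 2) and slc12a1 (-0.0902 to 0.344, without 40 ppt replicate 1 and 2, and -0.0046 without 30 ppt replicate 1). The cholesterol median in gill at 10 ppt was -1.39 to 0.187, without 30 ppt replicate 1 and 2. The cause of these shifts was not tested.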

Other observations

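All tests of explanations below were chosen only after the results were seen. Thyroid follicle markers, read from gill pieces, had a median log2 fold change of -4.40 at 10 against 40 ppt (5 genes, 0 called over all genes, 1 fell adjusted over the list alone, camera adjusted p = 0.00348, adjusted p = 0.574 with an estimated correlation). Their library medians were -2.21 and -1.13 at 10 ppt, -1.21 and 2.16 at 30 ppt, and 1.95 and 1.73 at 40 ppt. On log2 CPM their median was -3.96 with all libraries, -2.45 without 10 ppt replicate 1 and -2.52 without 40 ppt replicate 1. Interferon response genes in gill lay higher at 10 than at 40 ppt, 10 of 11 above 0 (0 called, median 0.34, camera adjusted p = 0.000467, adjusted p = 0.750 with an estimated correlation). That call was lost without 40 ppt replicate 2, where the median on log2 CPM was 0.19 against 0.36 with all libraries (camera adjusted p = 0.115), and the median was 0.59 without 40 ppt replicate 1.

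The matrix list lay lower in the 30 ppt libraries of gill and kidney, and skeletal genes in those of gill (at 10 and 40 ppt, 4 and 9 of 18 matrix and 3 and 4 of 12 skeletal genes rose in gill, and 0 in kidney, with adjusted p = 0.617 and 0.687 in gill and, for the matrix list, 0.509 and 0.402 in kidney with an estimated correlation). A single 30 ppt library is argued against by medians of edgeR fold changes of the matrix list that kept at least 0.830 of their size in kidney (10 against 30 ppt without 30 ppt replicate 2) and 0.966 in gill. Skeletal tissue like that in gill, as the source of the kidney rise, is argued against by a col10a1 to col1a2 ratio of at most 0.00638 of that in gill. It is also argued against by acan at 0.268 CPM at 40 ppt, where a rise of 18.9 would be needed. Of the 12 skeletal genes, matn4 went the other way, rising by 3.08 and 1.33 times the needed amount at 10 and 40 ppt. So did bglap at 40 ppt, by 3.71 times the needed amount, against 0.09 at 10 ppt. The gene matn3 rose by 0.39 of it at 40 ppt. Apart from matn4, matn3 and bglap, no gene rose by more than 0.148 of it at either salinity. Counts of bglap of 18 and 233 at 40 ppt, against 0 and 4 at 10 ppt and 0 at 30 ppt, leave a contribution of bone in 40 ppt replicate 2 open. More cartilage in the gill pieces cannot be told apart from regulation, because in 3 of 4 values acan and matn1 lay below the list median by more than 2 standard errors, and 1 did not. Water source cannot be told apart from salinity, because the matrix median was 0.92 in gill at 10 ppt, with the same sign at 40 ppt, and water source follows the groups in one reading of the labels.

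Liver transcripts lay higher in kidney at 30 ppt (12 genes, 0 called over all genes, 9 adjusted over the list alone against each other salinity, adjusted p = 0.674 and 0.860 with an estimated correlation). Liver tissue in the piece of replicate 2 may account for them there, as 10 of 12 hepatocyte genes were highest in that library. That count comes from the values that raised the question, so it is not independent support. Why replicate 1 also lay above the other kidney libraries stays open.

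Immediate early genes lay higher at 40 than at 10 ppt in both tissues, all 17 in each (0 called over all genes, 5 in gill and 7 in kidney adjusted over the list alone, adjusted p = 0.574 and 0.154 with an estimated correlation). A single library is argued against by medians of edgeR fold changes that kept at least 0.808 of their size without any 1 library of either salinity, and on log2 CPM the kidney median went from -0.84 to between -1.03 and -0.63. Time or handling between netting and sampling cannot be told apart from salinity, because the median was -0.82 in kidney with the same sign in gill, and the order of sampling is not given.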
